A study of Mus musculus with 6 samples.

How the data were processed

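RNA was measured in the thoracic aorta of 6 male mice, 5 to 7 weeks old, 1 library per animal. All animals carried floxed alleles of Yap1 and Wwtr1 and received 1 mg of tamoxifen per day for 5 days. Per the labels, the 3 knockout animals also carried a tamoxifen-inducible Cre recombinase driven by the smooth muscle gene Myh11, and the 3 controls did not. The tissue was taken on day 7 after the first injection. Animals are named by group and the animal number of the labels: controls 788, 785 and 787, knockouts 759, 782 and 780. Each library was treated as a separate animal, since each label carries its own number.

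Per the labels' protocols, RNA was extracted with a Qiagen kit and libraries were made with a stranded mRNA kit from Illumina, with 13 PCR cycles in place of 15. The submitters' processing notes name bcl2fastq, FastQC, HISAT2, StringTie and DESeq2, without versions, and the mouse genome build GRCm38. The strand setting of the counting and the annotation release are not given in the sources used here. Selection of polyadenylated RNA makes the values of short non-coding RNAs unreliable, and antisense or overlapping genes could share reads.

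The deposited gene tables list, per the file headers, coverage, FPKM and TPM for each gene. The authors' TPM values (transcript abundances scaled to a fixed total) sum to 1000000 in each library and their FPKM values are fragments per kilobase scaled to the library's depth. The deposited coverage is the signal per base of the gene's exons. TPM was used for all main results, FPKM for an alternative and coverage only for depth. The tables hold no read counts, so a log-scale linear model was used and no count model. Each table listed 54532 gene IDs. Between 5 and 9 IDs per library stood on several rows, and the values of those rows were summed. Of the IDs, 54495 were in the GENCODE release vM21 annotation of the same build, which supplied gene types. Coordinates are those of the deposited tables.

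TPM keeps no depth, but StringTie's FPKM is the coverage of a gene scaled by the library. In genes with 1 annotated transcript and FPKM above 10, the ratio of coverage to FPKM was within 1% of its median for 99.83% of genes in every library, which gave the aligned sequence in gigabases. It was 2.83 to 3.34 in the controls and 3.42 to 3.99 in the labelled knockouts, so every labelled knockout library was deeper than every control. The number of reads was not derived, and counting error per gene is therefore not given.

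Values were analysed as log2(TPM + 1) for the 15229 genes with a mean TPM of at least 1 over the 6 libraries. A fold change on this scale understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a variance trend and no covariates, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Errors of log2 fold changes are limma's moderated standard errors, and errors of TPM are SD over 3 animals. Exact permutation tests of 3 against 3 cannot give a p below 0.1. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

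Lists of genes, 28 with 776 entries, were written from general knowledge before the data were examined, as were the groups, the tests and most of the alternatives. Of the entries, 773 were found in the tables. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and the rotation test fry were alternatives. The rule for named genes was also fixed then. It took Yap1 and Wwtr1, and in each direction the 10 genes with the largest log2 fold change among those past the threshold. These also needed groups that did not overlap, a mean TPM of at least 5 in the higher group and a descriptive symbol, and 1 of those that were lower is not reported here. From each list it took up to 4 members past the threshold with the largest change, or the 2 with the highest mean TPM where none passed. Genes named outside that rule are said to have been chosen after their values were seen.

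The gene test was tested on simulated values with the means and residual spread of these 15229 genes, in 5 draws with 200 changed genes each. It recovered 47.6% of genes changed 2-fold and 84.0% of genes changed 4-fold, and 5.60% of calls were false. Genes were simulated as independent, so shifts that many genes share within a library are not part of these rates. The alternatives changed the pseudocount, the filter on low values, the unit, the scaling between libraries, the variance model, the set test and the libraries included. A library set without control 787 and knockout 780, and a covariate for brown fat markers, were added after seeing the data. No sample was left out of the main results.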

Results

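Transcript levels were measured by RNA sequencing in the thoracic aorta of 6 male mice, 3 controls and 3 labelled as inducible smooth muscle knockouts of Yap1 and Wwtr1. Yap1 and Wwtr1, the latter encoding TAZ, are transcriptional co-activators restrained by the Hippo pathway. Cre recombinase was under the Myh11 promoter, which is active in smooth muscle, so other aortic cells were not targeted. The controls lacked Cre, and all animals received tamoxifen. The comparison asks how the aortic transcriptome differed between the labelled groups 7 days after the first injection. Aligned sequence was 2.83 to 3.34 gigabases per control library and 3.42 to 3.99 per labelled knockout library. Between 14936 and 15225 genes per library had a TPM of at least 1. The mitochondrial genome took 5.92% to 6.39% of TPM in the controls and 6.38% to 9.33% in the labelled knockouts.

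The targeted genes did not match the labels as totals per gene. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, GRCm38) stood at 34.0, 95.0 and 87.7 TPM in controls 788, 785 and 787. It stood at 38.3, 42.3 and 16.3 TPM in labelled knockouts 759, 782 and 780. Its log2 fold change was -1.11 ± 0.48 with a limma adjusted p of 0.294, and the groups overlapped (exact two-sided permutation p = 0.3). Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910) was not lower in any labelled knockout library than in any control. It stood at 80.4, 77.6 and 72.3 TPM in the same controls and 89.8, 115 and 96.3 TPM in the labelled knockouts. The log2 fold change was 0.38 ± 0.12 with a limma adjusted p of 0.173, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. A gene total also holds reads from exons outside a floxed segment and from cells without Cre, and values per exon were not analysed here. Since these values do not bear out the labels, every direction given here is that of the libraries labelled knockout against those labelled control.

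**Figure D1:**
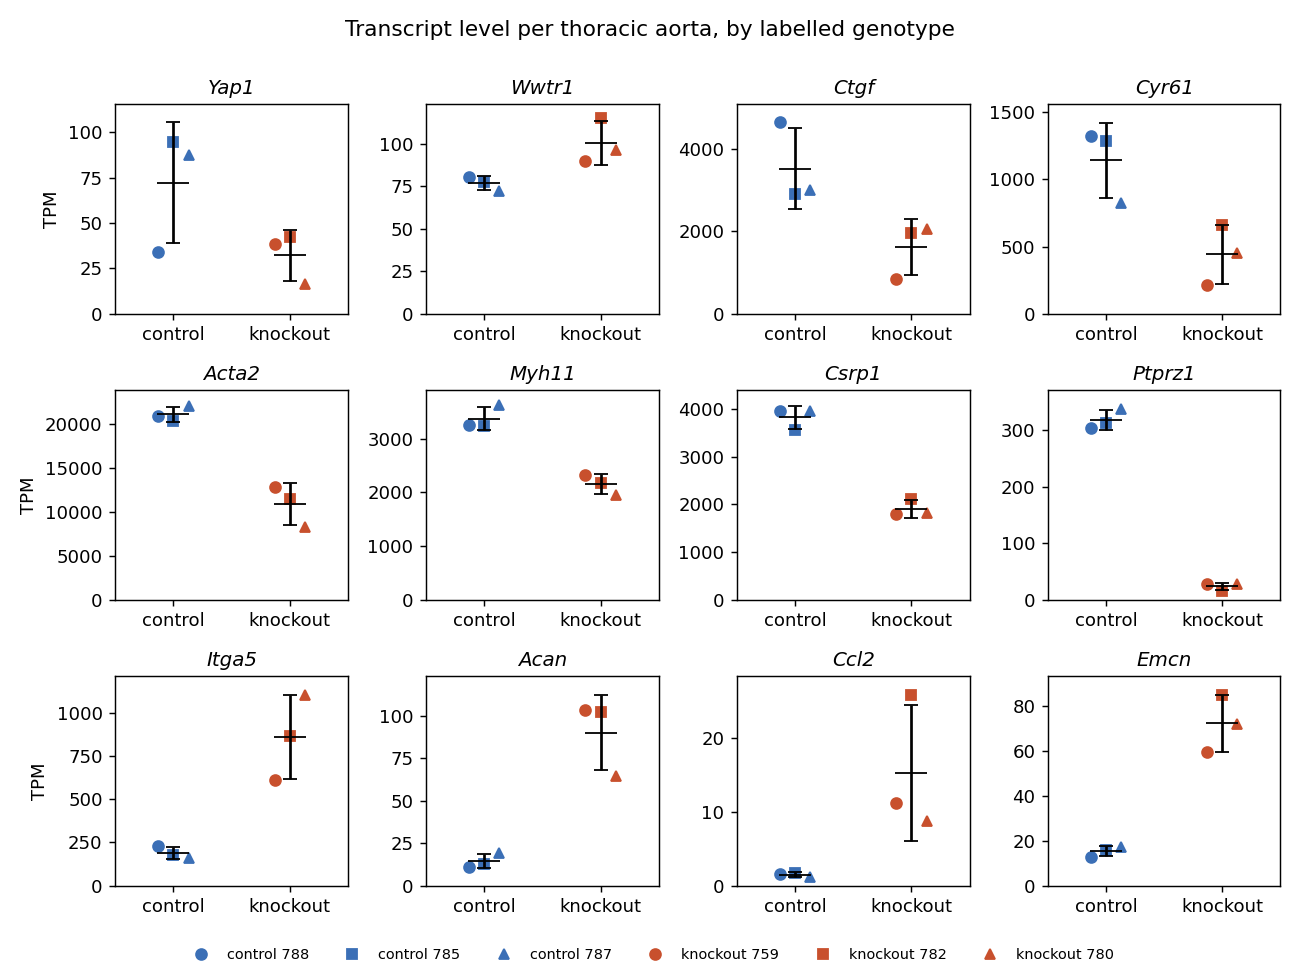
TPM of 12 genes in each of the 6 aortas (points), with the mean and SD over 3 animals per labelled group (bars). Control 788 had a Yap1 value of 34.0 TPM, below labelled knockouts 759 and 782. The groups did not overlap for any other gene shown. Of these, Wwtr1, Ctgf, Cyr61, Acta2 and Myh11 did not pass the limma threshold.

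Between the labelled groups, 181 of 15229 genes passed the threshold, 78 higher and 103 lower in the labelled knockouts. A change of at least 2-fold was reached by 49 of the higher and 60 of the lower genes. All 181 had groups that did not overlap, as did 22.9% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2618 genes, against 761 by chance. The count depended on each library. It was 43, 80 and 23 without control 788, 785 and 787, and 709, 74 and 88 without knockout 759, 782 and 780. The first principal component held 43.8% of the variance, and labelled knockout 759 lay between the controls and the other labelled knockouts on it.

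Among the genes with the largest falls, Ptprz1, a receptor tyrosine phosphatase (chromosome 6, 22875502 to 23052916), fell 13.6-fold, from 318 ± 17.1 TPM in controls to 23.4 ± 6.82 in the labelled knockouts (SD, n = 3 each). Its log2 fold change was -3.75 ± 0.21 with a limma adjusted p of 0.00294. Adamts8, a secreted metalloprotease (chromosome 9, 30942562 to 30963838), fell from 40.8 ± 1.54 to 3.97 ± 1.21 TPM. The myosin-binding protein gene Mybpc2 stood at 11.7 ± 1.00 TPM in controls and at 0.881, 0 and 0.857 TPM in the labelled knockouts. Mylk4, a myosin light chain kinase family gene, fell from 425 ± 29.5 to 70.8 ± 26.1 TPM, and Tnnt1, the slow skeletal troponin T gene, from 32.1 ± 6.56 to 8.18 ± 3.35. The Ras-like gene Rasl11a fell 3.92-fold. The ephrin receptor gene Epha1 fell from 14.3 ± 0.833 to 3.19 ± 1.26 TPM and the zinc finger gene Zfp580 from 13.7 ± 2.09 to 1.24 ± 0.432. Zyx, at a mean of 332 TPM, overlaps Epha1 on the opposite strand. The strand setting of the counting is not given, so that pair could share reads. Snord57, a small nucleolar RNA inside Nop56 on the same strand, fell from 8.07 ± 1.996 to 0.651 ± 0.968 TPM, and its reads cannot be separated from those of its host. Limma adjusted p-values of these genes were 0.00294 to 0.0342.

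Among the genes with the largest rises, Htatip2 (chromosome 7, 49759115 to 49773975) was near 0 in controls, at 0.0811, 0.127 and 0 TPM, and at 10.4, 22.0 and 20.9 TPM in the labelled knockouts. Its log2 fold change was 4.07 ± 0.29 with a limma adjusted p of 0.00466. Rasd1, a Ras family gene induced by glucocorticoids, rose 10.3-fold to 35.5 ± 10.8 TPM. The bone morphogenetic protein family gene Gdf6 rose from 2.25 ± 0.575 to 25.9 ± 14.0 TPM, and the retinol and steroid dehydrogenase gene Dhrs9 from 1.53 ± 0.240 to 16.9 ± 9.39. Tesc, encoding the calcium-binding protein tescalcin, rose from 6.75 ± 1.20 to 42.9 ± 14.1 TPM. Acan, which encodes the cartilage proteoglycan aggrecan, rose from 14.5 ± 4.31 to 90.1 ± 22.1 TPM. Itga5, the fibronectin receptor alpha chain, rose from 188 ± 35.1 to 861 ± 245 TPM. The chemokine gene Ccl2 and the endothelial adhesion gene Sele rose 10.1-fold and 11.4-fold from means of 1.51 and 1.04 TPM. The endothelial sialomucin gene Emcn rose from 15.3 ± 2.25 to 72.2 ± 12.7 TPM. Limma adjusted p-values of these 10 genes were 0.00466 to 0.0366.

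**Figure D2:**
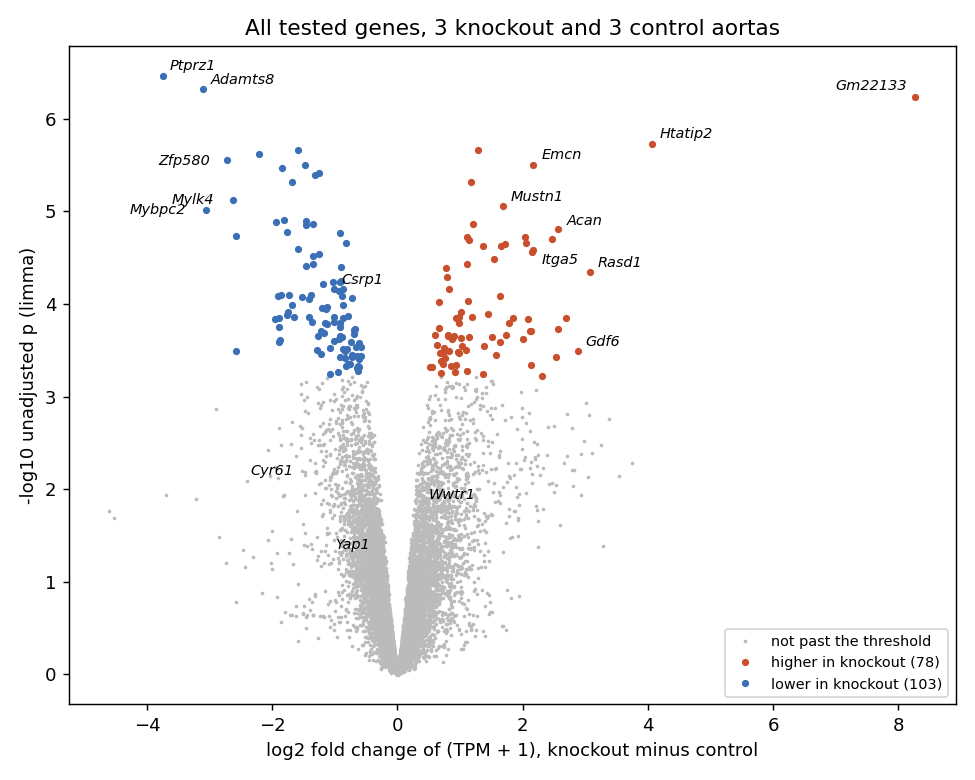
Unadjusted limma p (-log10, vertical axis) against the log2 fold change of TPM + 1, labelled knockout minus control (horizontal axis), for 15229 genes. Coloured points are the 78 higher and 103 lower genes past the adjusted threshold; Yap1 and Wwtr1 are among the grey points.

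None of the 22 tested YAP/TAZ target genes passed the threshold over all genes. The targets Ctgf and Cyr61, secreted matricellular proteins, had the highest levels. Ctgf stood at 3519 ± 982 TPM in controls and 1617 ± 674 in the labelled knockouts, with a log2 fold change of -1.19 ± 0.37 (-1.42 to -0.78 without 1 library) and a limma adjusted p of 0.165. Cyr61 stood at 1144 ± 280.3 and 442 ± 221 TPM, with -1.48 ± 0.40 and a limma adjusted p of 0.127. Neither gene's groups overlapped. The target Ankrd1, chosen after its values were seen, stood at 39.0, 23.9 and 32.7 TPM in controls 788, 785 and 787. It stood at 4.64, 10.3 and 116 TPM in labelled knockouts 759, 782 and 780, with -0.72 ± 1.00. Labelled knockout 780 also held Myh6, a cardiac myosin, at 174 TPM. Ankrd1 was not followed over the alternatives. Of the 22 targets, 14 had fold changes below 0 and 8 above 0. In the target list 4 genes with a negative and 2 with a positive fold change had an unadjusted p under 0.05. Adjusted over the list alone, 2 rose and 0 fell: Igfbp3, with a log2 fold change of 1.27 ± 0.24, and F3, with 0.55 ± 0.13, both chosen after their values were seen. The median log2 fold change of the list was -0.18 (-0.22 to -0.12 without 1 library), with a camera adjusted p of 0.319. Of 20 Hippo pathway components, 1 fell, also adjusted over the list alone. It was Vgll3, a TEAD cofactor, which went from 31.6 ± 2.54 to 12.7 ± 3.36 TPM (limma adjusted p = 0.0292). That list had a camera adjusted p of 0.154.

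Of the 38 contractile smooth muscle genes, 3 fell and 2 rose, and 33 did not pass. Adjusted over the list alone, 13 fell and 6 rose. Csrp1, a LIM protein of smooth muscle, fell from 3833 ± 237 to 1909 ± 186 TPM (limma adjusted p = 0.0185). The tropomyosin gene Tpm1 fell from 1386 ± 138 to 825 ± 45.2 TPM. Ppp1r12b, a myosin phosphatase subunit named after its values were seen, had a log2 fold change of -0.61 ± 0.09. Itga5 and Mustn1, a small musculoskeletal nuclear protein gene, rose, the latter from 378 ± 51.8 to 1224 ± 183 TPM. Further smooth muscle genes, chosen after their values were seen, did not pass. Acta2, the smooth muscle actin gene, stood at 21059 ± 849 and 10853 ± 2365 TPM (limma adjusted p = 0.0801), and Myh11 at 3378 ± 221 and 2153 ± 188 (limma adjusted p = 0.0632). Tagln had a log2 fold change of -0.54 ± 0.17 and Cnn1 of -0.03 ± 0.15. The list lay lower as a whole, with a median of -0.26 (-0.32 to -0.13 without 1 library) and a camera adjusted p of 0.00459. With an estimated correlation its adjusted p was 0.383. The means of the adipocyte and brown fat lists were higher in each labelled knockout library than in any control. The same held for several other lists, among them TGF-beta signalling, immediate early genes and endothelial cell markers. It did not hold for the proliferation or the macrophage and monocyte lists.

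Contractile receptors and ion channels had 0 of 38 members past the threshold in limma, with 4 higher and 3 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone, and a camera adjusted p of 0.931. Atp2a2 and Itpr1 had log2 fold changes of -0.05 ± 0.13 and -0.21 ± 0.12. Caveolae had 0 of 8 in limma and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.848), where Cavin1 and Ehd2 had -0.31 ± 0.14 and 0.23 ± 0.11. Of 43 elastic and collagen matrix genes, Vcan, encoding the proteoglycan versican, rose from 64.2 ± 0.410 to 109.7 ± 16.5 TPM. Mfap4, a microfibril-associated protein gene, fell from 702 ± 66.3 to 372 ± 27.1 TPM. Adjusted over the list alone 2 rose and 1 fell, and the list's camera adjusted p was 0.993. Of 20 matrix proteases and inhibitors, the gelatinase gene Mmp2 fell from 281 ± 8.68 to 158 ± 7.15 TPM, and adjusted over the list alone 4 rose and 3 fell. The camera adjusted p was 0.651.

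In the TGF-beta signalling list, 2 of 27 members rose and 1 fell, and adjusted over the list alone 6 rose and 3 fell. Id1, an inhibitor of basic helix-loop-helix factors, rose from 43.8 ± 6.59 to 90.1 ± 13.0 TPM, and Bmp6 from 49.8 ± 4.40 to 81.8 ± 8.96. Txndc5, at a mean of 299 TPM, overlaps Bmp6 on the opposite strand, and the pair could share reads. The matrix gene Tgfbi fell from 407 ± 31.7 to 241 ± 33.5 TPM. The list had a median of 0.26 (0.14 to 0.29 without 1 library) and a camera adjusted p of 0.0140. The adjusted p was 0.338 with an estimated correlation, and 0.00482 with fry, the only list past the threshold there. Of 18 cartilage and bone genes, Acan rose, and 7 rose and 1 fell adjusted over the list alone. The list had a median of 0.28 (0.17 to 0.38 without 1 library) and a camera adjusted p of 0.00423, or an adjusted p of 0.338 with an estimated correlation.

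Inflammatory cytokine and adhesion genes rose in 4 of 38 cases, and in 14, against 1 that fell, adjusted over the list alone. Besides Ccl2 and Sele these were Lcn2, an iron-binding lipocalin, from 0.596 ± 0.314 to 5.53 ± 1.91 TPM, and Vcam1, a leukocyte adhesion gene, from 65.8 ± 8.52 to 124 ± 12.9. The list's median was 0.67, or 0.38 to 0.88 without 1 library (camera adjusted p = 4.3e-07, adjusted p = 0.355 with an estimated correlation). Control 787 had the lowest mean of both this list and the macrophage and monocyte list, and labelled knockouts 782 and 780 had the highest means of both. Among 25 immediate early genes, Arc and Egr3 rose, to 12.4 ± 4.27 and 6.10 ± 1.16 TPM from 2.05 ± 0.746 and 2.27 ± 0.197. All 25 had fold changes above 0, and 11 rose adjusted over the list alone. The camera adjusted p was 2.5e-09, and the adjusted p was 0.355 with an estimated correlation. Of 19 circadian clock genes, the clock output gene Tef rose from 44.8 ± 7.62 to 116 ± 10.4 TPM, and 5 rose and 2 fell adjusted over the list alone. The camera adjusted p was 0.0104 (adjusted p = 0.355 with an estimated correlation). Dbp, another output gene chosen after its values were seen, stood at 246 TPM in labelled knockout 759 and at 32.2 to 50.7 TPM in the other libraries.

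Several lists had positive medians and camera calls with few or no members past the gene threshold. No member passed in limma for proliferation (32), sterol biosynthesis (22) or oxidative phosphorylation (45), where 13, 9 and 26 members were higher at an unadjusted p under 0.05. Adjusted over the list alone 0, 0 and 22 rose. Their medians were 0.93 (0.56 to 1.32 without 1 library), 0.50 and 0.36, with camera adjusted p of 3.0e-08, 9.2e-06 and 4.6e-11. With an estimated correlation the adjusted p was 0.411, 0.355 and 0.355. Their most abundant members had log2 fold changes of 0.50 ± 0.19 (Mcm6), 0.20 ± 0.12 (Pcna), 0.48 ± 0.34 (Fdps), 0.59 ± 0.29 (Hmgcs1), 0.45 ± 0.14 (Atp5b) and 0.40 ± 0.13 (Cox4i1). The proliferation mean of labelled knockout 759 was 2.43 on the log2 scale, within the controls' 2.08 to 2.59, and that of 782 and 780 was 3.72 and 3.35. The sterol biosynthesis mean of 759 was 4.63, within the controls' 4.44 to 4.65, and that of 782 and 780 was 5.14 and 5.11. The means of the oxidative phosphorylation and brown fat lists ranked the 6 libraries alike, and ran from 7.31 to 7.82 and from 2.25 to 5.31 on the log2 scale. Of 27 p53 and DNA damage genes the death receptor gene Fas fell from 127 ± 8.55 to 67.0 ± 1.06 TPM, against the list's positive median of 0.23 (0.14 to 0.28 without 1 library). Adjusted over the list alone 3 rose and 1 fell, with a camera adjusted p of 0.00575 and an adjusted p of 0.338 with an estimated correlation. The means of the p53 list ranked the libraries as those of the brown fat list did, apart from controls 788 and 787. Of 33 unfolded protein and amino acid stress genes, 1 fell, also adjusted over the list alone. It was the lipoprotein receptor gene Vldlr, from 86.6 ± 3.57 to 53.6 ± 4.03 TPM, while the list's median was 0.16. The camera adjusted p was 0.0210 (adjusted p = 0.338 with an estimated correlation). Interferon response genes passed in 0 of 39 cases in limma, with 5 higher and 2 lower at an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 1 fell. Ifi27l2a and Bst2 had 1.47 ± 0.30 and 0.39 ± 0.13, and the camera adjusted p was 0.0371 (adjusted p = 0.688 with an estimated correlation).

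**Figure D3:**
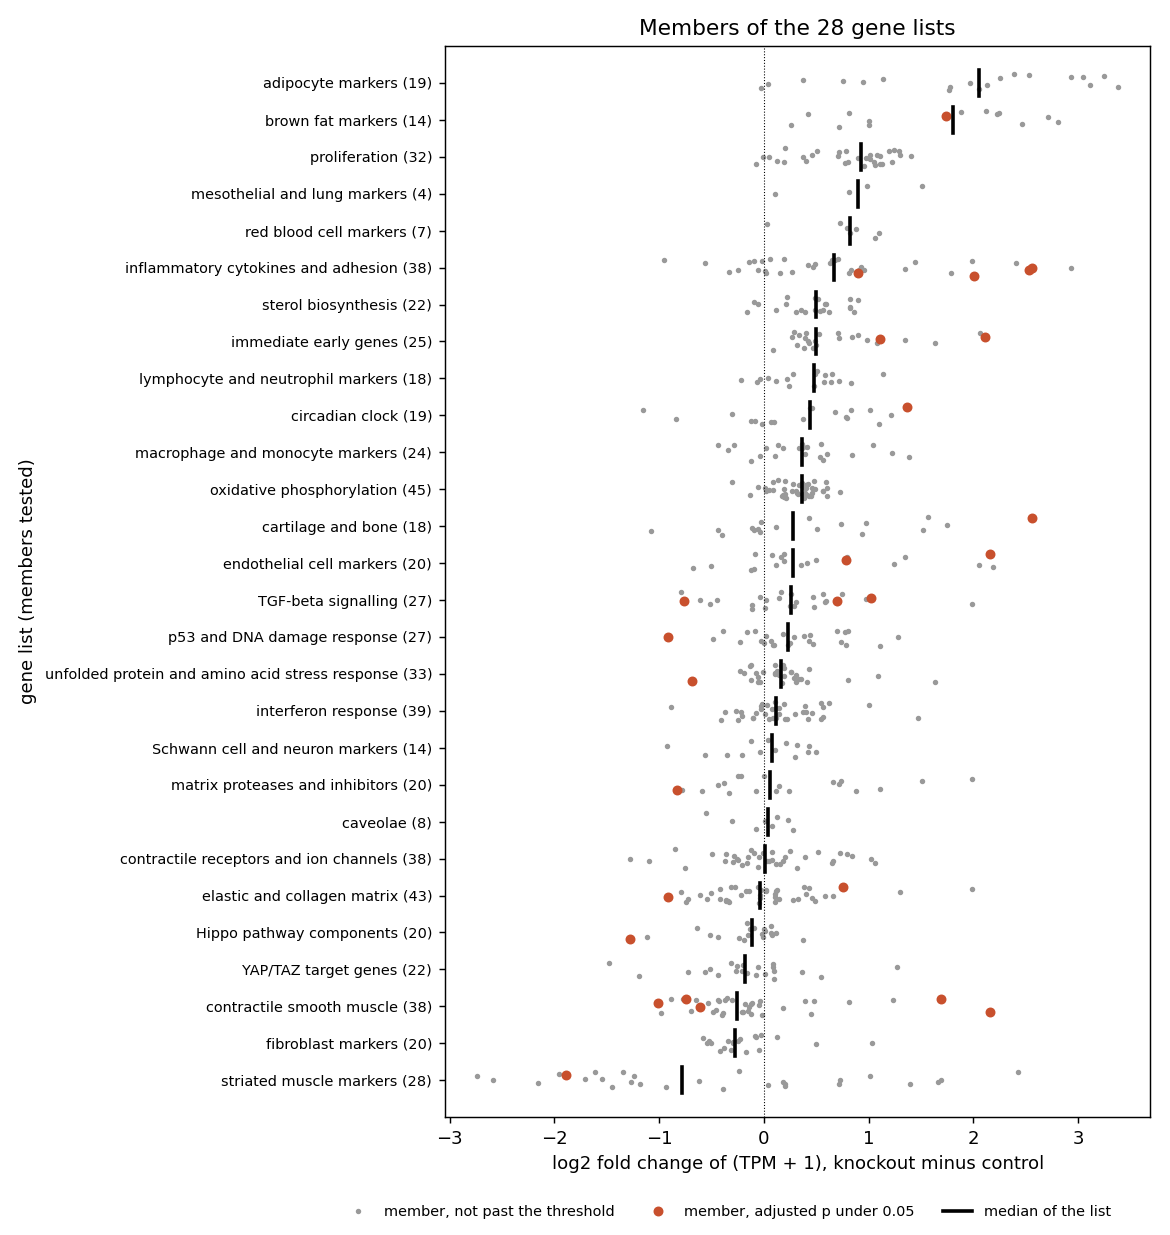
Log2 fold change of TPM + 1, labelled knockout minus control, for each tested member of the 28 lists (points; members past the limma threshold larger and coloured) with the list median (bar). Medians ran from -0.78 for striated muscle markers to 2.05 for adipocyte markers.

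The mean of the adipocyte list was 4.47, 6.43 and 5.05 on the log2 scale in controls 788, 785 and 787. It was 6.88, 7.22 and 7.51 in labelled knockouts 759, 782 and 780. None of its 19 members passed in limma, 14 were higher at an unadjusted p under 0.05, and 14 rose adjusted over the list alone. Fabp4, a fatty acid carrier, stood at 461 ± 293 and 1733 ± 522 TPM and the desaturase gene Scd1 at 428 ± 315 and 719.6 ± 292. Adipoq, the adiponectin gene chosen after its values were seen, stood at 35.1 ± 38.1 and 207 ± 94.2 TPM. Of 14 brown fat markers the potassium channel gene Kcnk3 rose from 9.55 ± 1.56 to 35.2 ± 11.3 TPM, and 7 rose adjusted over the list alone. Ucp1, the thermogenic uncoupling protein chosen after its values were seen, stood at 75.2 ± 67.9 and 229.7 ± 79.6 TPM. Camera adjusted p was 9.3e-10 and 1.2e-07 for the 2 lists, and the adjusted p was 0.355 for both with an estimated correlation.

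Endothelial markers rose in 2 of 20 cases, Emcn and the TGF-beta co-receptor gene Eng, the latter from 72.0 ± 1.20 to 124 ± 7.36 TPM, and in 9 adjusted over the list alone. The list's camera adjusted p was 1.6e-04, and the adjusted p was 0.355 with an estimated correlation. The means of the endothelial list ranked the libraries as those of the brown fat list did, apart from controls 788 and 787. Fibroblast markers had 0 of 20 past the threshold in limma, with 8 lower and 2 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone. The list's median was -0.27, with a camera adjusted p of 0.0140 (adjusted p = 0.383 with an estimated correlation). Dcn and Gsn had log2 fold changes of -0.32 ± 0.15 and -0.17 ± 0.18. Macrophage and monocyte markers had 0 of 24 past the threshold in limma, 2 higher at an unadjusted p under 0.05, and a camera adjusted p of 0.00477, or an adjusted p of 0.583 with an estimated correlation, with Lyz2 at 0.37 ± 0.35 and Cd74 at -0.13 ± 0.50. Lymphocyte and neutrophil markers had 0 of 18, also at an unadjusted p under 0.05, and a camera adjusted p of 0.0569, with Ighm at -0.06 ± 0.64 and Igkc at 0.58 ± 1.19. Red blood cell markers had 0 of 7 over all genes, 3 higher at an unadjusted p under 0.05 and 2 higher adjusted over the list alone. Their camera adjusted p was 0.00283 (adjusted p = 0.430 with an estimated correlation). The haemoglobin genes Hbb-bs and Hba-a1, which have near-identical copies, had 0.80 ± 0.40 and 1.10 ± 0.30. The mean of the red blood cell list was 7.64 in labelled knockout 759, while 782, at 6.37, lay below control 788, at 6.43, and the median log2 fold change of the list was 0.36 to 1.10 without 1 library. Schwann cell and neuron markers had 0 of 14, with 1 higher and 2 lower at an unadjusted p under 0.05, Pmp22 at -0.35 ± 0.39 and Ncam1 at -0.04 ± 0.15 and a camera adjusted p of 0.489. Mesothelial and lung markers had 0 of 4, also at an unadjusted p under 0.05, with Krt18 at 0.11 ± 0.25 and Msln at 1.51 ± 1.11 and a camera adjusted p of 0.195. Of 28 striated muscle markers Tnnt1 fell, 2 fell adjusted over the list alone, and the camera adjusted p was 0.156.

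Single libraries carried transcripts of striated muscle. Acta1, skeletal actin, stood at 167 TPM in control 787 and below 1 in the other libraries. Myh6, a cardiac myosin, stood at 174 TPM in labelled knockout 780 and at 1.18 to 8.37 elsewhere. Both were chosen after their values were seen. Without these 2 libraries, which left 2 animals per group, 3 genes passed the threshold, with 1720 at an unadjusted p under 0.05. With the mean of the brown fat markers as a covariate, 0 genes passed in limma, with 735 at an unadjusted p under 0.05. That covariate follows the groups and leaves fewer degrees of freedom, so the loss of calls does not show that fat is the cause.

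**Figure D4:**
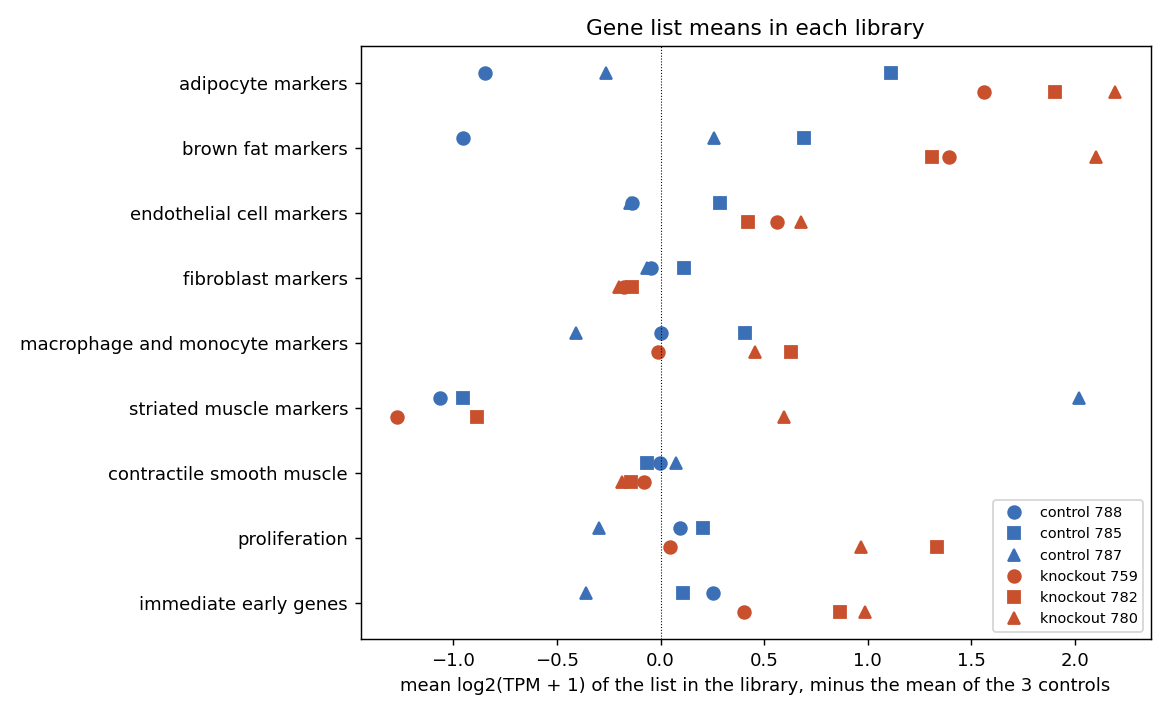
Mean log2(TPM + 1) of 9 lists in each library, as the difference from the mean of the 3 controls (horizontal axis), 1 point per animal. All 3 labelled knockout libraries lie above the controls for adipocyte, brown fat and endothelial markers and immediate early genes. They lie below the controls for fibroblast markers and contractile smooth muscle genes. Control 787 lies highest for striated muscle markers.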

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

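Leaving out control 787 and knockout 780 together, and the brown fat covariate, were alternatives added after seeing the data, and a list's direction was defined by the sign of its members' median after a first version had used camera's direction. All of the 181 genes that were tested in an alternative kept their direction. Since their groups did not overlap, this was fixed in advance except where the unit, the scaling or the covariate changed. The count of 181 (78 higher, 103 lower) fell to 64 (28, 36) with no filter on low values and to 114 (49, 65) without the variance trend, and rose to 1111 (520, 591) with array weights. Leaving out 1 library gave 23 to 709 genes, 12 to 306 higher and 11 to 403 lower. Leaving out both libraries with striated muscle transcripts left 3 genes (3 higher, 0 lower), with 2 animals per group. The brown fat covariate left 0 (0 higher, 0 lower) in limma, with 735 at an unadjusted p under 0.05; it follows the groups and leaves fewer degrees of freedom. The other alternatives gave 158 to 194 genes, and no scaling moved the median of all genes by over 0.1. The share of lower genes, 56.9%, was 37.5% without control 785.

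Of the 28 lists 18 passed with camera at the preset correlation, 0 with an estimated correlation and 1 with fry; other settings gave 15 to 20. Leaving out 1 library gave 16 to 20. It moved medians by over 1.5 times for the lists whose ranges without 1 library are given in the results above, and for further lists. Among further lists that had passed, the ranges were 0.19 to 0.77 for the circadian clock list and 0.12 to 0.42 for the endothelial cell markers list. They were 0.36 to 0.85 for the immediate early genes list, 0.0040 to 0.19 for the interferon response list and 0.20 to 0.52 for the macrophage and monocyte markers list. Among results that had not passed, besides the YAP/TAZ target genes list given above, it did so for the Hippo pathway components list (-0.11 to -0.037) and the Schwann cell and neuron markers list (0.042 to 0.23). It also did so for the caveolae list (0.0060 to 0.048), the matrix proteases and inhibitors list (0.015 to 0.13) and the mesothelial and lung markers list (0.36 to 1.51). For single genes the ranges were 0.33 to 0.70 for Mcm6, 0.13 to 0.30 for Pcna, 0.16 to 0.81 for Fdps, 0.34 to 0.94 for Hmgcs1, -0.44 to -0.18 for Cavin1, 0.12 to 0.29 for Ehd2, -0.29 to -0.12 for Itpr1, -0.46 to -0.19 for Dcn, -0.35 to -0.010 for Gsn, 0.35 to 1.10 for Hbb-bs, 0.078 to 0.71 for Lyz2, -0.75 to -0.11 for Pmp22, 0.40 to 1.52 for Scd1, 1.10 to 3.06 for Ucp1, 0.20 to 1.502 for Dbp and 0.69 to 2.65 for Msln. Yap1 stayed short of the threshold, with adjusted p of 0.221 to 1.00 over the alternatives and a log2 fold change of -1.58 to -0.70 without 1 library. Wwtr1 passed with array weights, at 0.46 (adjusted p = 0.0469, range over the alternatives 0.0469 to 1.00), and was 0.27 to 0.45 without 1 library. The cause was not tested in either case.

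Of 50 named genes past the threshold, none changed sign, which groups that did not overlap fixed in advance for most alternatives. Among the results past the threshold, the sign turned for the interferon response list (-0.086 without both striated muscle libraries, -0.030 with the covariate) and for the brown fat markers list under its own covariate (-0.17). Other sign changes were in results that had not passed. With a minimum mean TPM of 5 these were the contractile receptors and ion channels list (-0.029), the matrix proteases and inhibitors list (-0.034), the Schwann cell and neuron markers list (-0.081) and the striated muscle markers list (0.11). With FPKM they were the contractile receptors and ion channels list (-0.00293), the Schwann cell and neuron markers list (-0.012) and the striated muscle markers list (0.12). With array weights they were the contractile receptors and ion channels list (-0.014), the elastic and collagen matrix list (0.041), Cd74 (0.11), Ighm (0.030) and Cnn1 (0.055). Without 1 library the ranges were -0.099 to 0.097 for the contractile receptors and ion channels list, -0.078 to 0.010 for the elastic and collagen matrix list, -0.066 to 0.83 for the lymphocyte and neutrophil markers list and -1.38 to 0.82 for the striated muscle markers list. For single genes they were -0.17 to 0.048 for Atp2a2, -0.48 to 0.40 for Cd74, -0.58 to 0.57 for Ighm, -0.27 to 1.75 for Igkc, -0.16 to 0.057 for Ncam1, -0.15 to 0.061 for Cnn1, -0.18 to 0.27 for Krt18 and -0.20 to 2.78 for Myh6. Without both striated muscle libraries the values were -0.048 for the contractile receptors and ion channels list, -0.00518 for the caveolae list, 0.028 for the elastic and collagen matrix list, -0.12 for the lymphocyte and neutrophil markers list, -0.014 for the Schwann cell and neuron markers list, -0.12 for Lyz2, -1.08 for Igkc, 0.12 for Ncam1 and 0.093 for Cnn1. With the covariate they were -0.074 for the contractile receptors and ion channels list, 0.00825 for the elastic and collagen matrix list, -0.00903 for the matrix proteases and inhibitors list, -0.33 for the mesothelial and lung markers list, -0.25 for Lyz2, -2.09 for Igkc, -0.28 for Scd1, -0.54 for Msln, 0.30 for Cnn1, -1.14 for Ucp1 and -1.65 for Myh6. The count test planned for raw counts was not run, since the tables hold none. No paired analysis was possible because the groups share no animal numbers. Depth in gigabases was higher in every labelled knockout, while the number of genes at a TPM of at least 1 overlapped between the groups.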

Other observations

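The tests of the library label, exons, fat, clock and immediate early genes below were chosen after the values they concern had been seen, except the first placement of the libraries and the splits, whose criteria were written before their results. The genes in the next paragraph were also chosen after their values were seen.

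Further genes past the threshold belonged to no list. The LIM domain gene Pdlim1 fell from 280.3 ± 23.6 to 148 ± 20.3 TPM, the actin-binding gene Nexn from 225 ± 23.5 to 138 ± 3.13, and the non-muscle myosin gene Myh10 from 408 ± 42.5 to 213 ± 19.2. Higher in the labelled knockouts were the small heat shock gene Hspb7, from 244 ± 14.1 to 552 ± 38.3 TPM, and the intermediate filament gene Nes, from 134 ± 8.78 to 301 ± 73.2. The antioxidant gene Srxn1 rose from 10.8 ± 4.50 to 46.6 ± 7.53 TPM, the electron transfer gene Etfb from 118 ± 11.9 to 243 ± 48.5, the adenine nucleotide carrier gene Slc25a5 from 261 ± 20.3 to 405 ± 19.2 and the lactate dehydrogenase gene Ldha from 237 ± 10.99 to 374 ± 9.17. Ftl1, the ferritin light chain gene, rose from 106 ± 4.56 to 458 ± 129.97 TPM. The short gene model Gm22133 lies inside Ftl1 on the same strand and went from 0.501 ± 0.842 to 468 ± 226 TPM. Reads of the pair cannot be told apart by position, and ferritin light chain has many pseudogenes. Etfb, Mybpc2, Ftl1 with Gm22133, Ldha and Htatip2 lie on chromosome 7 between 43444083 and 49773975, Mybpc2 lower and the others higher. Dbp, Tead2 and Bax in the same stretch did not pass. The share of called genes in that stretch was not counted, and a cause particular to it was not tested.

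Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 181 genes and the highest other gave 6, and 1 split, the real one, gave as many. Splits of this number are too few for a share under 0.05.

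Wwtr1 was not lower and Yap1 did not pass the threshold in the labelled knockouts, for which a wrong group label is a candidate explanation. A wrong label of 1 library leaves Wwtr1 unexplained, since each labelled knockout stood above every control, at 89.8 to 115 against 72.3 to 80.4 TPM. When each library was placed by the genes called in the other 5, 5 of 6 lay nearer to their own group, where the criterion against a wrong label had been all 6, and labelled knockout 759 lay marginally on the control side, at -0.02 on a scale from -0.5 at the control mean to 0.5 at the knockout mean. Labelled knockout 759 lay beyond all 3 controls toward the other labelled knockouts in 79.1% of 709 genes called without it. Left-out controls did so in 48.8% to 68.8% of 23 to 80 genes, but each only against the remaining controls, an easier bar. These shares were looked at after the placement, with no bound that could be reached, and do not decide the label. Ptprz1 stood at 27.0 TPM in 759 against 303 to 336 in the controls, and Htatip2 at 10.4 against 0 to 0.127. That 759 lay outside the controls in both was required by the rule that named them. A wrong label of 759 stays open, also for Yap1. The log2 fold change of Yap1 was -1.29 ± 0.55 without 759 and -1.58 ± 0.39 without 788, the control with the lowest value (limma adjusted p = 0.221 and 0.227). Control 788 and the other controls lay on their own side, which argues against an exchange of 759 with a single control. An exchange of the labels of the whole groups would leave each placement unchanged. The placement cannot speak to it, and it stays open. Reads from exons outside the deleted part stay open, since the tables hold 0 columns of values per exon, as do reads from cells without Cre, since the mix of cells may differ between the groups.

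In the labelled knockouts 3 of 38 contractile genes fell and 2 rose, and the contractile list lay lower and the adipocyte list higher with camera at the preset correlation (adjusted p = 0.383 and 0.355 with an estimated correlation). A lower share of smooth muscle cells as the only change would raise all other cell types alike. The adipocyte minus fibroblast difference changed by 3.65 standard errors (exact two-sided permutation p = 0.1). Adipocyte markers had already been seen to lie higher and fibroblast markers lower, so this test could hardly come out otherwise. A lower share of smooth muscle cells alongside more fat stays open. More perivascular fat in the samples is a candidate explanation. Fat that dilutes all other cells alike, as the whole cause, is argued against by 42.1% of contractile members lying over 2 standard errors from the list's median. That criterion was set after the members' values had been seen. It followed a first criterion, on the contractile minus fibroblast difference, which had come out in favour of fat. The difference changed by 0.035 ± 0.099, or 0.35 standard errors (exact two-sided permutation p = 0.9). The first criterion is not used because its bound against fat was nearly out of reach. Fat as part of the cause stays open, as does an effect of genotype.

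In the labelled knockouts 2 of 25 immediate early and 1 of 19 clock genes rose, and both lists passed with camera at the preset correlation (adjusted p = 0.355 for each with an estimated correlation). Collection at another time of day would move output genes such as Dbp against opposite-phase genes such as Arntl. That difference changed by 1.72 standard errors, most of it from labelled knockout 759, which leaves the time of day open. Handling of the tissue before freezing could raise the immediate early genes in some animals. Their within-group SD was 0.418 of the group difference, between the bounds set for either outcome, so handling and genotype cannot be told apart here.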
